A study of Homo sapiens with 8 samples.

How the data were processed

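Gene expression was measured by RNA sequencing in 8 samples, 2 from each of 4 groups: the lines called SKNBE2 and KPNYN in the sample titles, each treated for 21 days with doxycycline at 0.5 mg/mL (unit as the labels give it) or with vehicle. Groups and replicate numbers came from the sample titles. Those titles and the series design name SKNBE2, while the source names, the treatment protocol and the header of the deposited normalized table name Kelly for the same samples; the title's name is used throughout. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

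Per the labels' protocols, RNA was isolated with a Qiagen kit and libraries were made and sequenced by Novogene as 150 bp paired-end reads on a NovaSeq. Trimmomatic, FastQC, STAR, featureCounts and DESeq2, and the builds GRCh37 and hg19, are named per the submitters' processing notes; versions, settings and the annotation release are not given in the sources used here. The deposited count files hold whole-number read or fragment counts for 25702 Entrez gene identifiers per library, with no normalization by the authors. The deposited normalized table holds a signal per gene for 15735 genes, and each of its columns was its library's count divided by one size factor (0.937 to 1.12); that table was used only for gene symbols and for this check. Symbols came from it for 15189 identifiers and from the NCBI RefSeq table of GRCh38.p14 for 8595, and 1918 had none. That assembly is not the authors' build, so it served only for names and for the order of neighbouring genes, and coordinates are not given. The strand setting of the counting is not stated, so reads of a gene and of an antisense partner cannot be separated, and genes with near-identical copies are uncertain.

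Library totals ran from 16642809 to 25000348 counts, and the 10 genes with most counts took 4.61% to 8.45% of a library. A floor of 3 counts equalled 0.140 to 0.167 CPM in a single library. Where both libraries of a group had a count of 0, a fold was computed against 3 counts over the group and written as a lower bound, and where a group had 1 to 3 counts the ratio of pooled counts is given with its exact 95% counting interval. These folds and the floor are scaled by TMM like CPM. Intervals and floors cover counting error only. Replicates differed by more than sampling noise, with a chi-square per gene of 3.97 and 3.27 in SKNBE2 with vehicle and doxycycline and 6.56 and 2.59 in KPNYN, so all 8 libraries were kept as separate samples.

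The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test. One fit held all 8 libraries with a mean per group (4 residual degrees of freedom), TMM scaling and the filterByExpr low-count filter, which left 16235 genes; p-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. TMM factors were 1.03 to 1.08 except in the KPNYN doxycycline libraries (0.862 and 0.860). Comparisons were doxycycline against vehicle in each line, the difference of these (KPNYN minus SKNBE2) and KPNYN against SKNBE2 with vehicle. For a log2 fold change ± is an approximate standard error (SE) from its test, unreliable at few counts. For CPM, scaled by TMM, it is the SD over 2 libraries. Of 16235 simulated genes, 100 were changed at each size. The test recovered 93% of log2 changes of 1 and 100% of 2 in SKNBE2, and 97% and 99% in KPNYN. False calls were 7 and 18 (3.50% and 8.41% of calls). Changes at low counts or in most genes were not simulated.

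The design, the 30 gene lists, the naming rule and the alternatives were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, which compares a list with all other genes, and adjusted over the 30 lists. Only members that passed the low-count filter entered, and the list sizes given are of these members. No list call held with an estimated correlation. Another test, fry, asks whether the members of a list move one way on balance and does not compare them with other genes. List medians are of fitted values, and those of the 2 responses are also given with members without a count in one group set at their bound where this changes them; fitted differences between lines of such genes depend on the prior count. The genes named are PRRX1 and 18 fixed genes; the 6 largest rises and falls per line with an adjusted p below 0.05 and a mean of at least 5 CPM in the higher group; up to 4 members per list that passed, by adjusted p; the 4 largest each way for the difference between lines and for the vehicle-treated lines; and the 6 each way with the largest smaller change in both lines. Y-linked genes and XIST are left out, and some other genes are not reported here. List members that moved against the rest of their list, and those given for both directions of a list, were named after their values were seen.

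Alternatives were DESeq2 size factors in edgeR, library size alone, the Wald test of DESeq2 1.42.0, no low-count filter (at least 1 count), at least 5 CPM in 2 libraries, each line fitted alone, the replicate number as a block, a test against a log2 fold change of 1 (glmTreat), each library left out in turn, and for lists a prior count of 0.5, an estimated correlation and fry. Groups of 2 are too small for a test of outlying libraries or of other splits of the samples, and neither was made. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.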

Results

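RNA sequencing measured gene expression in 2 human neuroblastoma cell lines carrying a tetracycline-inducible (tetON) copy of PRRX1, a homeobox transcription factor of mesenchymal tissue. Each line received doxycycline, which switches the construct on, at 0.5 mg/mL (the labels' unit) for 21 days, or vehicle. Each of the 4 groups had 2 libraries. One line is KPNYN. The other is called SKNBE2 here after its sample titles, but other labels give Kelly, and which line it was is unresolved. Total counts were 20394089 and 18001035 in SKNBE2 with vehicle, 17451890 and 17545412 in SKNBE2 with doxycycline, 16642809 and 18438270 in KPNYN with vehicle, and 22388473 and 25000348 in KPNYN with doxycycline. On the log2 CPM scale the first principal component held 63.5% of the variance and the second 24.6%, and the 2 libraries of each group lay next to each other on both. The comparisons ask what 21 days of forced PRRX1 expression changed in each line, above all in adrenergic, mesenchymal and GD2 ganglioside synthesis genes, whether the lines responded alike, and how they differed without it.

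PRRX1 rose in both doxycycline-treated libraries of both lines. Its counts went from 180 and 183 to 10848 and 11571 in SKNBE2 and from 60 and 82 to 43300 and 49328 in KPNYN. In CPM (counts scaled to a common library total, mean ± SD, n = 2 libraries per group here and below) PRRX1 (Entrez 5396) went from 9.16 ± 0.940 to 616 ± 20.3 in SKNBE2, a log2 fold change of 6.08 ± 0.08 (± SE here and below; adjusted p = 6.4e-21). In KPNYN it went from 3.74 ± 0.580 to 2270.3 ± 36.2 CPM, a log2 fold change of 9.24 ± 0.10 (adjusted p = 1.6e-23). The counts do not separate the construct from the cells' own PRRX1 gene, and as doxycycline-treated cells without the construct are not used here, effects of the drug and of PRRX1 are not separated.

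**Figure D1:**
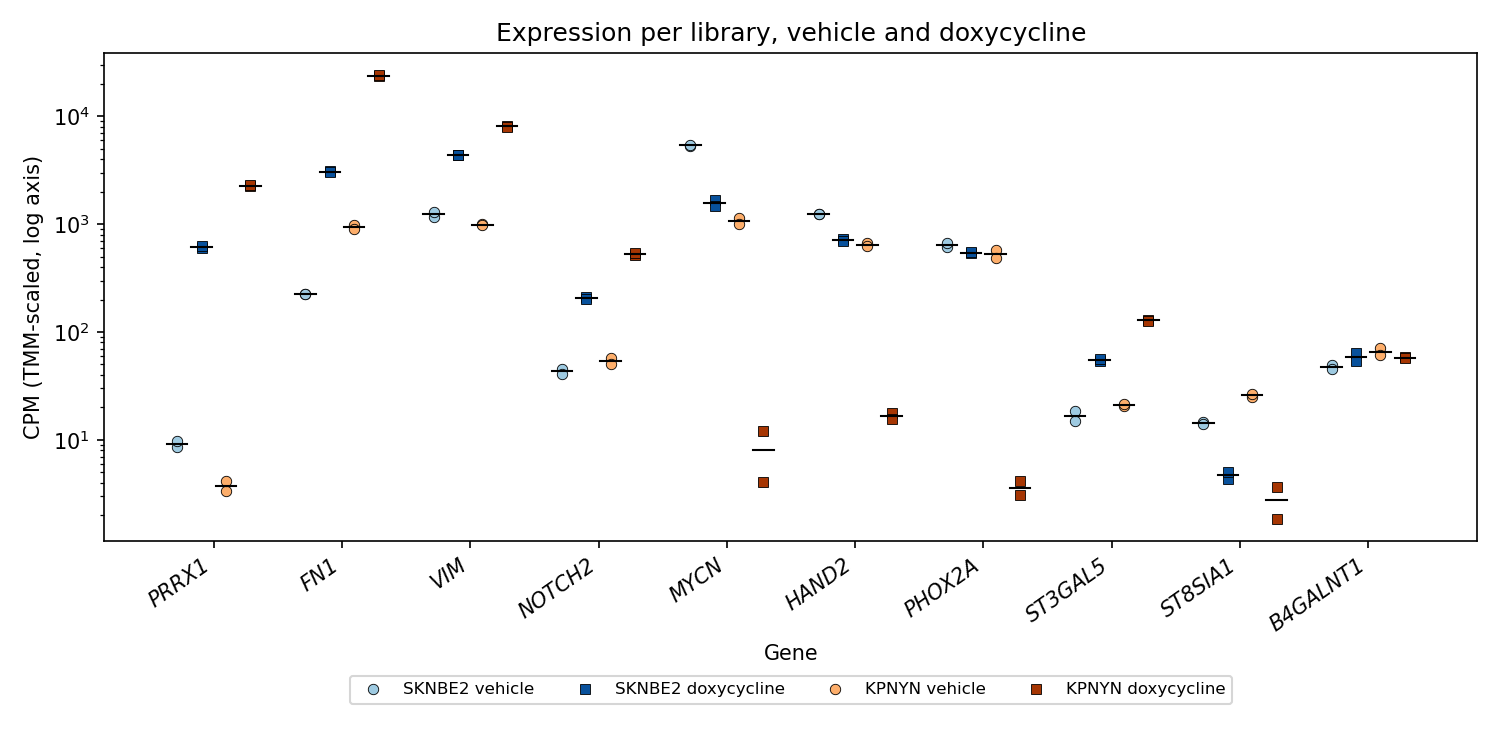
CPM of PRRX1 and genes of the fixed set in each library on a log axis, with one point per library and bars at the group means. PRRX1 averaged 616 CPM with doxycycline in SKNBE2 and 2270.3 CPM in KPNYN, and the neuroblast gene PHOX2A averaged 546 and 3.61 CPM in the same groups.

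In SKNBE2, doxycycline raised extracellular matrix and antigen presentation genes and lowered part of the adrenergic neuroblast programme. FN1 (Entrez 2335), which encodes the matrix protein fibronectin, rose from 224 ± 0.500 to 3066 ± 28.3 CPM (log2 fold change 3.77 ± 0.06, adjusted p = 1.8e-20). VIM (Entrez 7431), the intermediate filament of mesenchymal cells, rose from 1232 ± 91.5 to 4384 ± 52.6 CPM (1.83 ± 0.06). MYCN (Entrez 4613), the amplified oncogene of many neuroblastomas, fell from 5381 ± 81.7 to 1564 ± 141 CPM (-1.78 ± 0.14). Of 16235 genes tested, 9636 changed at an adjusted p below 0.05, 5051 upward and 4585 downward. Changes beyond 2-fold were mostly rises, with 2571 genes up and 728 down.

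Of the 21 adrenergic core transcription factors tested, 2 rose and 16 fell (2 and 16 adjusted over the list alone) in SKNBE2. Their median was -0.51 (camera adjusted p = 4.4e-05, adjusted p = 0.069 with an estimated correlation). Those that fell included TFAP2B (-1.57 ± 0.06), ISL1 (-1.64 ± 0.07) and SIX3 (-1.84 ± 0.09), all factors of neuroblast or neural progenitor identity, with adjusted p of 6.4e-13 or less. HAND2 (Entrez 9464) and GATA3 (Entrez 2625), 2 factors of the sympathetic lineage, fell by less (-0.82 ± 0.06 and -0.51 ± 0.06). PHOX2A (Entrez 401), a homeobox factor of the same lineage, fell from 643 ± 36.7 to 546 ± 0.825 CPM (-0.24 ± 0.07, adjusted p = 0.0093), a call lost without SKNBE2 vehicle replicate 2 (adjusted p = 0.10; 5.5e-05 to 1.0 over all alternatives). HEY1 (0.27 ± 0.10) rose. Among 13 genes of catecholamine synthesis and storage, 3 rose and 8 fell (3 and 8 adjusted over the list alone). The median was -1.17 (camera adjusted p = 0.073), with the granule proteins CHGB (-2.14 ± 0.08) and CHGA (-1.94 ± 0.08) and the cofactor enzyme GCH1 (-2.48 ± 0.12) lower and the granule protein SCG2 (1.37 ± 0.06) higher. Of 17 neuronal structure genes, 2 rose and 14 fell (2 and 14 adjusted over the list alone). Their median was -0.70 (camera adjusted p = 2.1e-04, adjusted p = 0.096 with an estimated correlation). Examples were neurofilament NEFL (-1.49 ± 0.06), the growth cone gene GAP43 (-1.48 ± 0.07), the synaptic gene SNAP25 (-1.40 ± 0.07) and doublecortin DCX (-1.09 ± 0.06).

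GD2, a disialoganglioside on neuroblasts, is made from ceramide in steps that the 6 listed genes encode, and in SKNBE2 4 rose and 2 fell (4 and 2 adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.34). ST8SIA1 (Entrez 6489), the GD3 synthase, fell from 14.3 ± 0.471 to 4.70 ± 0.524 CPM (-1.61 ± 0.18, adjusted p = 2.4e-07). ST3GAL5 (Entrez 8869), the GM3 synthase, rose from 16.6 ± 2.47 to 54.8 ± 1.29 CPM (1.73 ± 0.09, adjusted p = 2.1e-12). UGCG (Entrez 7357), the glucosylceramide synthase, and B4GALT6 (Entrez 9331), a lactosylceramide synthase, also rose (0.81 ± 0.10 and 0.97 ± 0.17), while the other lactosylceramide synthase, B4GALT5 (Entrez 9334), fell (-0.30 ± 0.06). B4GALNT1 (Entrez 2583), which converts GD3 to GD2, rose from 47.6 ± 2.88 to 58.9 ± 7.16 CPM (0.31 ± 0.09, adjusted p = 0.0071), but without SKNBE2 vehicle replicate 2 or SKNBE2 doxycycline replicate 1 the adjusted p was 0.090 or 0.21 (0.0020 to 1.0 over all alternatives). Among 12 other neuroblastoma surface antigens, 2 rose and 6 fell (3 and 6 adjusted over the list alone). Their median was -0.08 (camera adjusted p = 0.33; median -0.13 with DESeq2 size factors), with DLK1 (-5.20 ± 0.14), a Notch-ligand relative, the receptor kinase ALK (-1.76 ± 0.08) and the noradrenaline transporter SLC6A2 (-1.29 ± 0.08) lower and the adhesion molecule L1CAM (0.69 ± 0.06) higher.

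Of the 30 mesenchymal transcription factors other than PRRX1, 25 rose and 0 fell (25 and 0 adjusted over the list alone). The median was 1.42 (camera adjusted p = 3.1e-08, adjusted p = 0.069 with an estimated correlation). The AP-1 subunit FOSL1 (4.57 ± 0.10), the skeletal factor RUNX2 (5.67 ± 0.19), the receptor NOTCH2 (2.26 ± 0.07; Entrez 4853) and the DNA sensor IFI16 (2.30 ± 0.08) rose, as did SNAI2 (Entrez 6591), a repressor active in epithelial-mesenchymal transition (1.69 ± 0.09). In the epithelial-mesenchymal transition list of 18, 16 rose and 2 fell (16 and 2 adjusted over the list alone). Their median was 2.28 (camera adjusted p = 3.4e-07, adjusted p = 0.096 with an estimated correlation). Examples were tenascin C TNC (4.67 ± 0.08), the phospholipid-binding annexin ANXA1 (5.06 ± 0.08) and the fibronectin receptor subunit ITGA5 (4.27 ± 0.09), while the transition regulators TWIST1 (-1.13 ± 0.07) and ZEB1 (-0.22 ± 0.06) fell. Of 22 collagen and matrix genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone). The median was 2.12 (camera adjusted p = 4.0e-10, adjusted p = 0.12 with an estimated correlation). Among them were THBS1 (3.96 ± 0.07), COL12A1 (5.13 ± 0.10) and THBS2 (3.86 ± 0.08) and the collagen cross-linking oxidase LOXL2 (3.46 ± 0.07). The 10 fibroblast markers, of which 5 are also in the matrix list, moved with them, as 9 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 1.56 (camera adjusted p = 6.9e-05, adjusted p = 0.096 with an estimated correlation), with COL1A1 (4.14 ± 0.10) and COL3A1 (2.32 ± 0.09), the surface protein THY1 (1.22 ± 0.06) and the surface protease FAP (4.56 ± 0.23). All 12 YAP/TAZ targets rose (12 adjusted over the list alone). The median was 3.86 (camera adjusted p = 9.2e-09, adjusted p = 0.069 with an estimated correlation). These included the matricellular genes CYR61 (4.04 ± 0.08) and CTGF (4.29 ± 0.09).

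Smooth muscle and TGF-beta response genes rose as well: of 13, 12 rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 2.61 (camera adjusted p = 8.8e-06, adjusted p = 0.096 with an estimated correlation), with smooth muscle actin ACTA2 (4.14 ± 0.08), transgelin TAGLN (3.69 ± 0.09) and the receptor TGFBR2 (3.63 ± 0.11). Of 11 Notch pathway genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). The median was 1.65 (camera adjusted p = 0.0054, adjusted p = 0.31 with an estimated correlation). Among them were the ligand JAG1 (1.81 ± 0.11) and the receptor NOTCH1 (3.18 ± 0.20), with the feedback gene NRARP (-0.78 ± 0.15) lower. For 13 AP-1 and immediate early genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 0.093). Members included IER3 (2.16 ± 0.12) and FOSL2 (1.29 ± 0.08). Of 15 genes of MHC class I antigen presentation, 14 rose and 1 fell (14 and 1 adjusted over the list alone). The median was 2.85 (camera adjusted p = 9.2e-06, adjusted p = 0.10 with an estimated correlation). These included the non-classical molecule HLA-E (4.49 ± 0.16), the loading factor TAPBP (1.85 ± 0.09), the transactivator NLRC5 (3.15 ± 0.15) and the immunoproteasome subunit PSMB9 (6.20 ± 0.35); reads of HLA-B and HLA-C can be split between near-identical copies, so their values are uncertain. Of 19 interferon-stimulated genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). Their median was 2.20 (camera adjusted p = 1.5e-05, adjusted p = 0.069 with an estimated correlation). Examples were the interferon signalling factor IRF9 (2.20 ± 0.13), the antiviral gene IFIT3 (3.98 ± 0.26) and the RNA sensor DDX58 (2.51 ± 0.18), with OAS3 (-0.77 ± 0.10) lower. Among 10 natural killer cell ligands, 7 rose and 1 fell (7 and 1 adjusted over the list alone). The median was 1.68 (camera adjusted p = 0.018, adjusted p = 0.12 with an estimated correlation), with the adhesion ligand ICAM1 (8.19 ± 0.21), the nectin NECTIN2 (3.54 ± 0.13) and the NKG2D ligands MICA (4.59 ± 0.26) and MICB (4.50 ± 0.27) higher, this pair being similar enough to share reads.

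Cell cycle, ribosome biogenesis and nuclear oxidative phosphorylation genes were modestly lower in SKNBE2. None of 20 cell cycle genes rose and 17 fell (0 and 17 adjusted over the list alone). Their median was -0.49 (camera adjusted p = 6.7e-06, adjusted p = 0.10 with an estimated correlation). Members included the replication helicase subunits MCM3 (-0.70 ± 0.06) and MCM7 (-0.63 ± 0.05). Of 16 MYC-family targets of ribosome biogenesis, 0 rose and 15 fell (0 and 15 adjusted over the list alone). The median was -0.58 (camera adjusted p = 9.2e-06, adjusted p = 0.096 with an estimated correlation). These included fibrillarin FBL (-1.22 ± 0.06) and the polyamine enzyme ODC1 (-0.78 ± 0.06). Of 16 nuclear genes of oxidative phosphorylation, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was -0.57 (camera adjusted p = 6.7e-06, adjusted p = 0.18 with an estimated correlation). Examples were NDUFV1 (-0.90 ± 0.06) and CYCS (-0.94 ± 0.06). Of 13 mitochondrially encoded genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation), and these took 2.68% and 3.12% of counts with vehicle and 3.79% and 3.93% with doxycycline. Among 11 PRC2 components, 2 rose and 5 fell (2 and 5 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.099), and EZH2 (Entrez 2146), its histone methyltransferase, fell (-0.46 ± 0.07). Among 14 p53 targets, 8 rose and 2 fell (8 and 2 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.093), with the death receptors TNFRSF10B (3.04 ± 0.11) and FAS (3.97 ± 0.29) and the cell cycle inhibitor CDKN1A (2.45 ± 0.13) up. For 15 integrated stress response genes, 3 rose and 8 fell (4 and 8 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 0.17; the mean was 0.02, opposite in sign to the median). Of 14 hypoxia and glycolysis genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.11). Among them were NDRG1 (2.98 ± 0.10) and ADM (2.31 ± 0.08). Of 8 heat shock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 0.80 (camera adjusted p = 0.038, adjusted p = 0.33 with an estimated correlation). Members included the co-chaperones BAG3 (1.85 ± 0.09) and DNAJB1 (1.10 ± 0.08).

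Among 10 neural crest genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone) in SKNBE2. The median was 0.28 (camera adjusted p = 0.49), with the homeobox gene MSX1 (3.13 ± 0.26) and the transcription factor TFAP2A (3.61 ± 0.38) up and SOX4 (-0.72 ± 0.06) down. Of 8 limb and skeletal mesenchyme genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone). Their median was -0.06, or 0.01 with members at 0 set to their bound (camera adjusted p = 0.38; the mean was 0.27 and the test pointed down). Of 8 Schwann and glial markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 1.39 (camera adjusted p = 0.10). Among them were the neurotrophin receptor NGFR (1.21 ± 0.15) and myelin basic protein MBP (3.19 ± 0.62). Of 6 immune and endothelial markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone). Their median was 2.19 (camera adjusted p = 0.030, adjusted p = 0.15 with an estimated correlation). Those that rose were the endothelial receptor TIE1 (at least 93.0-fold higher), the monocyte receptor CD14 (2.90 ± 0.28), the endothelial cadherin CDH5 (2.19 ± 0.49) and von Willebrand factor VWF (2.04 ± 0.77). Of 4 epithelial markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone). The median was 1.95 (camera adjusted p = 0.22). Those that rose were the keratins KRT18 (5.14 ± 0.10) and KRT8 (3.99 ± 0.31), which have many pseudogenes. In SKNBE2 18 of 30 lists passed camera with its preset correlation. With an estimated correlation 0 passed, 12 had an unadjusted p below 0.05, and fry called 29.

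The largest rises in SKNBE2 with at least 5 CPM were from no vehicle count in either library. They were C3 (at least 294-fold higher), GALNT5 (at least 142-fold higher), KRT34 (at least 125-fold higher), TIE1 (at least 93.0-fold higher), TRIM22 (at least 81.0-fold higher) and SIRPB1 (at least 70.4-fold higher), which encode the central complement component, an O-glycosylation enzyme, a hair keratin, an endothelial receptor, an interferon-induced antiviral protein and a signal-regulatory protein (adjusted p of 5.0e-10 or less). The largest falls were those of DLK1 (-5.20 ± 0.14), EDN3 (-5.14 ± 0.38), INSM2 (-4.67 ± 0.11), TBC1D3P1-DHX40P1 (-4.55 ± 0.42), GFRA3 (-4.28 ± 0.26) and ROBO2 (-3.72 ± 0.15), with adjusted p of 1.1e-08 or less. EDN3 is the ligand endothelin 3, INSM2 a neuroendocrine zinc finger factor, GFRA3 a receptor of the GDNF family and ROBO2 an axon guidance receptor. TBC1D3P1-DHX40P1 is a readthrough transcript of pseudogenes, whose reads can belong to related copies.

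In KPNYN the neuroblast programme fell far, for some genes to a few counts, while most matrix genes and mesenchymal transcription factors rose. HAND2 fell from 645 ± 30.4 to 16.7 ± 1.38 CPM (log2 fold change -5.27 ± 0.08, adjusted p = 4.6e-22), PHOX2A from 532 ± 64.2 to 3.61 ± 0.760 CPM (-7.21 ± 0.12) and MYCN from 1071 ± 103 to 8.01 ± 5.60 CPM (-7.09 ± 0.21). The MYCN value was -8.04 without KPNYN doxycycline replicate 1 and -6.48 without replicate 2. FN1 rose from 944 ± 63.8 to 23818 ± 425 CPM (4.66 ± 0.06), 2.03% and 2.07% of all counts in the doxycycline libraries, and VIM from 991 ± 14.5 to 8096 ± 83.9 CPM (3.03 ± 0.06). Of 16235 genes tested, 12113 changed, 5927 upward and 6186 downward (48.9% upward), and beyond 2-fold 3274 rose and 3166 fell. Scaled by library size alone, the median over all genes shifted by -0.32 and 34.9% of 12711 calls were upward.

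Of the 21 adrenergic core transcription factors, 2 rose and 19 fell (2 and 19 adjusted over the list alone) in KPNYN. Their median was -3.74 (camera adjusted p = 2.4e-06, adjusted p = 0.056 with an estimated correlation). Besides HAND2 and PHOX2A, the falls included the HAND2 relative HAND1 (-6.39 ± 0.14), ISL1 (-3.74 ± 0.08) and GATA3 (-3.08 ± 0.07), while KLF7 (0.79 ± 0.12) and PBX3 (0.53 ± 0.08) rose. All 13 genes of catecholamine synthesis and storage fell (13 adjusted over the list alone). The median was -4.50 (camera adjusted p = 7.8e-06, adjusted p = 0.063 with an estimated correlation). Among them were the transporter SLC6A2 (-9.13 ± 0.15), the rate-limiting enzyme tyrosine hydroxylase TH (-8.01 ± 0.14) and CHGB (-6.53 ± 0.12) and CHGA (-8.43 ± 0.16). All 17 neuronal structure genes fell too (17 adjusted over the list alone). Their median was -5.90 (camera adjusted p = 4.8e-08, adjusted p = 0.056 with an estimated correlation). Members included DCX (-8.47 ± 0.10), the microtubule gene MAP2 (-7.27 ± 0.10), the filament INA (-5.58 ± 0.08) and the RNA-binding gene ELAVL3 (-8.38 ± 0.14). Among surface antigens, 2 of 12 rose and 10 fell (2 and 10 adjusted over the list alone). The median was -3.37 (camera adjusted p = 6.6e-04, adjusted p = 0.21 with an estimated correlation), with the receptor kinase RET (-7.59 ± 0.12) and the adhesion molecule NCAM1 (-3.76 ± 0.07) lower.

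Within GD2 ganglioside synthesis, 3 of 6 rose in KPNYN and 2 fell (3 and 3 adjusted over the list alone). Their median was 0.62 (camera adjusted p = 0.58; median 0.29 by library size alone, 3 up and 3 down). ST8SIA1 fell from 25.8 ± 0.974 to 2.75 ± 1.25 CPM (-3.25 ± 0.19, adjusted p = 2.4e-12) and B4GALT5 fell (-0.54 ± 0.06), while ST3GAL5 (2.61 ± 0.09), UGCG (1.42 ± 0.10) and B4GALT6 (1.44 ± 0.13) rose. B4GALNT1 had 65.8 ± 7.10 CPM with vehicle and 57.6 ± 1.06 with doxycycline (-0.19 ± 0.09, adjusted p = 0.063). Its adjusted p ranged from 4.1e-05 to 1.0 over the alternatives, and those that gave a call were library size alone (4.1e-05), without the low-count filter (0.034), with at least 5 CPM in 2 libraries (0.038), the replicate number as a block (0.045), without KPNYN vehicle replicate 2 (0.0052) and without SKNBE2 doxycycline replicate 1 or 2 (0.047 and 0.048).

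Of 30 mesenchymal transcription factors other than PRRX1, 25 rose and 3 fell (25 and 3 adjusted over the list alone) in KPNYN. The median was 1.89 (camera adjusted p = 3.2e-06, adjusted p = 0.056 with an estimated correlation). Among those that rose were FOSL1 (6.19 ± 0.10), the TAZ gene WWTR1 (8.79 ± 0.17), the cartilage factor SOX9 (4.81 ± 0.10), RUNX1 (5.01 ± 0.10) and NOTCH2 (3.30 ± 0.08). The T-box gene TBX18 (56.1-fold, 95% counting interval 15.2 to 469.7) and ID1 (-0.56 ± 0.07) fell. SNAI2, which is in the epithelial-mesenchymal transition list, rose as well (2.73 ± 0.08). In the epithelial-mesenchymal transition list, 15 of 18 rose and 2 fell (15 and 2 adjusted over the list alone). Their median was 4.07, or 3.94 with members at 0 set to their bound (camera adjusted p = 5.7e-06, adjusted p = 0.13 with an estimated correlation). Members included TNC (5.85 ± 0.07), ANXA2 (5.78 ± 0.07) and ANXA1 (6.37 ± 0.09), while the regulators SNAI1 (-3.36 ± 0.13) and TWIST1 (-1.68 ± 0.07) fell; ANXA2 has pseudogenes that can share its reads. Of 22 collagen and matrix genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone). The median was 3.49 (camera adjusted p = 8.0e-06, adjusted p = 0.25 with an estimated correlation). These included COL6A3 (7.06 ± 0.07), LOXL2 (6.03 ± 0.08), COL4A1 (4.22 ± 0.07) and COL3A1 (5.30 ± 0.09). Of 10 fibroblast markers, 6 rose and 3 fell (7 and 3 adjusted over the list alone). Their median was 1.74 (camera adjusted p = 0.14), with the proteoglycans DCN (-8.01 ± 0.19) and LUM (-0.85 ± 0.08) lower. All 12 YAP/TAZ targets rose (12 adjusted over the list alone). The median was 5.21 (camera adjusted p = 8.5e-07, adjusted p = 0.063 with an estimated correlation). Among them were CTGF (5.98 ± 0.08), the ectonucleotidase NT5E (5.11 ± 0.07) and MYOF (6.79 ± 0.09). Of 13 TGF-beta response genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 3.45 (camera adjusted p = 2.0e-04, adjusted p = 0.14 with an estimated correlation). By library size alone it was 3.12, with 9 up and 1 down. Members included ACTA2 (5.59 ± 0.08) and TAGLN (5.20 ± 0.08). Of 11 Notch pathway genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). The median was 2.47 (camera adjusted p = 0.015, adjusted p = 0.39 with an estimated correlation). These included JAG1 (4.27 ± 0.09) and NOTCH3 (3.54 ± 0.10). For AP-1 and immediate early genes, 8 of 13 rose and 4 fell (8 and 4 adjusted over the list alone). Their median was 1.20 (camera adjusted p = 0.14).

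Of 15 MHC class I presentation genes, 14 rose and 0 fell (14 and 1 adjusted over the list alone) in KPNYN. The median was 4.47, or 3.28 with members at 0 set to their bound (camera adjusted p = 3.2e-05, adjusted p = 0.13 with an estimated correlation). Among them were HLA-E (6.90 ± 0.18), the light chain B2M (2.57 ± 0.07), TAPBP (2.55 ± 0.08) and the trimming peptidase ERAP2 (4.47 ± 0.14). Among 19 interferon-stimulated genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone). Their median was 1.25 (camera adjusted p = 0.13), with DDX58 (2.76 ± 0.17), IRF9 (1.24 ± 0.12) and IFITM1 (4.28 ± 0.46) higher and the antiviral enzymes OAS1 (at least 22.3-fold lower) and OAS3 (-4.13 ± 0.51) lower. Of 10 natural killer cell ligands, 9 rose and 1 fell (9 and 1 adjusted over the list alone). The median was 2.45 (camera adjusted p = 0.0091, adjusted p = 0.13 with an estimated correlation), with ICAM1 (7.32 ± 0.19), NECTIN2 (3.97 ± 0.11) and MICA (6.14 ± 0.28) higher and the NKp30 ligand NCR3LG1 (-2.30 ± 0.10) lower.

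All 14 p53 targets rose in KPNYN (14 adjusted over the list alone). Their median was 1.47 (camera adjusted p = 4.0e-05, adjusted p = 0.063 with an estimated correlation). By library size alone it was 1.15, with 11 up and 0 down. Examples were CDKN1A (4.58 ± 0.09), TNFRSF10B (2.44 ± 0.08) and FAS (5.04 ± 0.21) and the RNA-binding gene ZMAT3 (2.25 ± 0.07). Of 20 cell cycle genes, 6 rose and 13 fell (6 and 13 adjusted over the list alone). The median was -0.68 (camera adjusted p = 0.057), and the helicase subunits MCM7 (-1.55 ± 0.06) and MCM6 (-1.38 ± 0.06) were among those that fell. Of 16 MYC-family targets, 1 rose and 13 fell (1 and 13 adjusted over the list alone). Their median was -0.79 (camera adjusted p = 0.0018, adjusted p = 0.20 with an estimated correlation). Members included FBL (-1.08 ± 0.06) and nucleophosmin NPM1 (-0.88 ± 0.06). Of 16 nuclear oxidative phosphorylation genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone). The median was -0.42 (camera adjusted p = 0.043, adjusted p = 0.51 with an estimated correlation; median -0.74 by library size alone, 1 up and 15 down), with ATP5B (-0.83 ± 0.06) lower and SDHA (0.89 ± 0.08) higher. Among 13 mitochondrially encoded genes, 0 rose and 4 fell (0 and 3 adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.35; median -0.45 by library size alone, 0 up and 13 down). They took 5.11% and 5.14% of counts with vehicle and 3.84% and 3.80% with doxycycline. Among PRC2 components, 4 of 11 rose and 5 fell (4 and 5 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.58; median -0.54 by library size alone, 3 up and 6 down), with EZH2 (-0.83 ± 0.07) and RBBP4 (-1.74 ± 0.06) lower. For integrated stress response genes, 6 of 15 rose and 8 fell (6 and 8 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 0.51; median -0.78 by library size alone, 4 up and 9 down), with the cystine transporter SLC7A11 (2.49 ± 0.08) higher and asparagine synthetase ASNS (-2.08 ± 0.07) lower. For hypoxia and glycolysis, 6 of 14 rose and 3 fell (6 and 3 adjusted over the list alone). The median was 0.03 (camera adjusted p = 0.38; median -0.29 by library size alone, 5 up and 6 down). Of 8 heat shock genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 1.11 (camera adjusted p = 0.025, adjusted p = 0.37 with an estimated correlation). Examples were HSPB1 (2.37 ± 0.08) and BAG3 (3.87 ± 0.14).

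Among neural crest genes, 4 of 10 rose in KPNYN and 6 fell (4 and 6 adjusted over the list alone). The median was -0.79 (camera adjusted p = 0.51), with the nuclear receptor NR2F2 (7.59 ± 0.15) higher and the transcription factor SOX4 (-3.27 ± 0.07) lower. Of 8 limb and skeletal mesenchyme genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone). Their median was -1.77 (camera adjusted p = 0.065), with the homeobox gene DLX5 (-4.39 ± 0.25) and the PRRX1 relative PRRX2 (-1.41 ± 0.10) lower. Among 8 Schwann and glial markers, 4 rose and 2 fell (4 and 2 adjusted over the list alone). The median was 0.96 (camera adjusted p = 0.58; median 0.64 by library size alone, 4 up and 3 down), with PMP22 (2.33 ± 0.09) higher and NGFR (-2.54 ± 0.29) and S100B (-3.59 ± 0.56) lower. Of 6 immune and endothelial markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Their median was 0.24, or 0.22 with members at 0 set to their bound (camera adjusted p = 0.71; median 0.08 by library size alone, 0 up and 1 down; the mean was -0.34, opposite in sign to the median and the test), with the monocyte receptor CD14 (1.14 ± 0.40) higher and the leukocyte phosphatase PTPRC (33.5-fold, 95% counting interval 5.58 to 1364) lower. Of 4 epithelial markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone). The median was 1.45 (camera adjusted p = 0.58), with KRT18 (6.06 ± 0.17) and KRT8 (235-fold, 95% counting interval 41.8 to 9329) higher and EPCAM (11.9-fold, 95% counting interval 2.92 to 104) and KRT19 (9.72-fold, 95% counting interval 2.99 to 50.0) lower. In KPNYN 16 of 30 lists passed camera with its preset correlation. With an estimated correlation 0 passed, 10 had an unadjusted p below 0.05, and fry called 28.

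The largest rises in KPNYN were those of TRIML2 (at least 391-fold higher), EREG (at least 291-fold higher), STX11 (at least 176-fold higher), MMP3 (at least 163-fold higher), ESM1 (10.65 ± 0.15) and IL6 (at least 124-fold higher), with adjusted p of 2.3e-12 or less. EREG is an epidermal growth factor receptor ligand, STX11 a syntaxin, MMP3 the matrix protease stromelysin, ESM1 an endothelial proteoglycan and IL6 an inflammatory cytokine. Among the largest falls, each to no count in either doxycycline library, were those of ZIC1 (at least 395-fold lower), JAKMIP1 (at least 324-fold lower), ZDHHC22 (at least 315-fold lower), CNGB1 (at least 266-fold lower) and LINC01105 (at least 259-fold lower), with adjusted p of 2.7e-14 or less. ZIC1 is a zinc finger factor of neural development, JAKMIP1 a microtubule-binding protein of neurons, ZDHHC22 a palmitoyltransferase and CNGB1 a cyclic nucleotide-gated channel subunit. LINC01105 is a long non-coding RNA, and as the strand setting of the counting is not stated, antisense reads at such genes cannot be separated.

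The 2 responses overlapped in direction more than independent lists of the same sizes would. Among the genes that changed most in both lines, MMP3 (8.72 ± 0.28), EREG (399.5-fold higher, 95% counting interval 136 to 1940.4), GALNT5 (at least 142-fold higher), IL6 (337-fold higher, 95% counting interval 60.1 to 13359) and ESM1 (192-fold higher, 95% counting interval 65.2 to 932) rose in SKNBE2, as did TRIM22 (at least 81.0-fold higher there and 7.44 ± 0.21 in KPNYN), and in KPNYN GALNT5 was 385-fold higher, 95% counting interval 68.8 to 15255. INSM2, ROBO2, FEV (-3.37 ± 0.17), an ETS factor, the glutamate receptor GRM8 (-3.14 ± 0.13) and the chemokine receptor CXCR4 (-2.73 ± 0.16) fell in SKNBE2, and in KPNYN INSM2 (-8.16 ± 0.21), ROBO2 (432-fold lower, 95% counting interval 77.1 to 17099), FEV (-6.82 ± 0.15), GRM8 (-6.74 ± 0.26) and CXCR4 (129-fold lower, 95% counting interval 43.9 to 629) fell further (adjusted p of the difference 7.6e-06 or less). MMP3 had 0 and 5 counts with vehicle in SKNBE2, and its value there was 7.64 without vehicle replicate 1 and a fitted 13.08 without replicate 2, which leaves a count of 0. In KPNYN, INSM2 had -7.47 without doxycycline replicate 1 and -9.77 without replicate 2, and GRM8 had -7.37 without replicate 1. Both lines raised 3641 genes, against 1844 for independent lists, and lowered 3176, against 1747. Of 7978 genes called in both, 6817 (85.4%) moved the same way, while 637 rose in SKNBE2 and fell in KPNYN and 524 did the reverse. The 2 comparisons share no library. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.543 and a Spearman rho of 0.565.

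**Figure D2:**
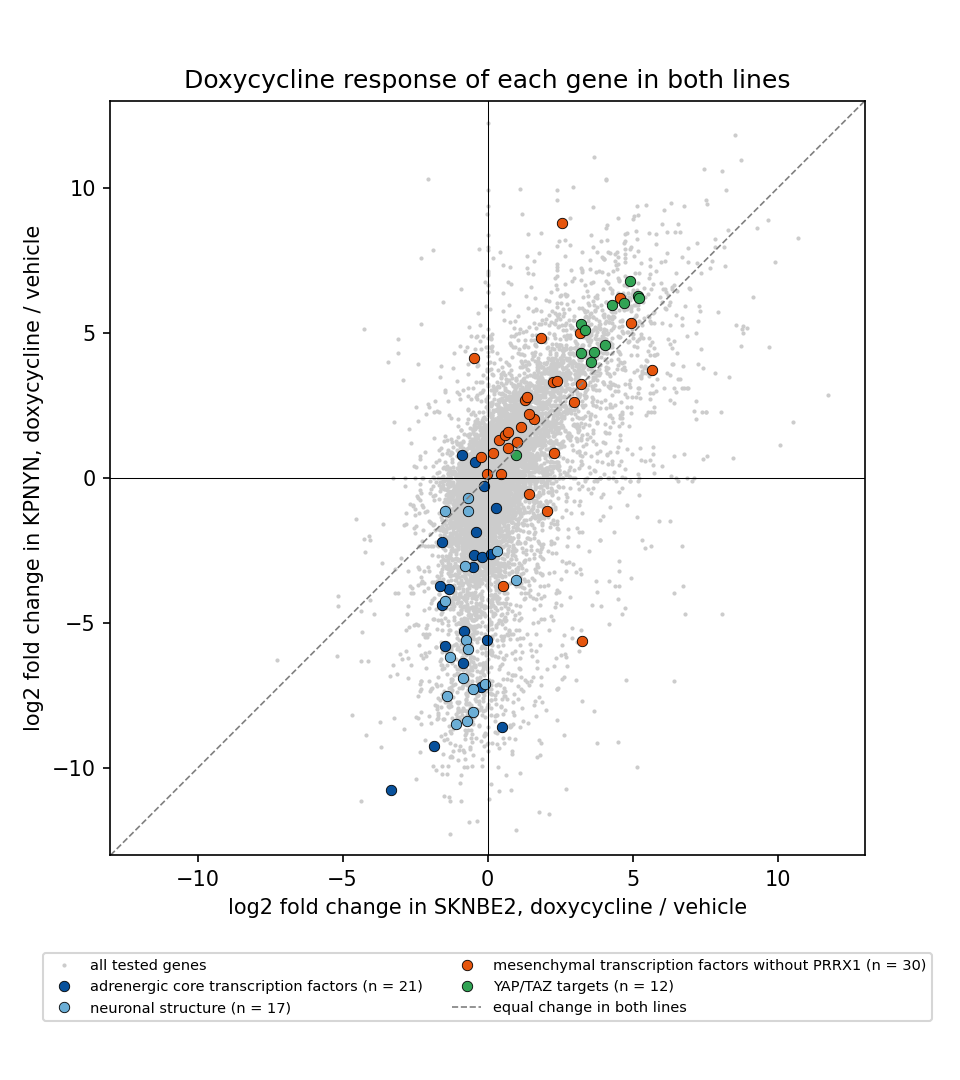
Fitted log2 fold change with doxycycline of every tested gene in SKNBE2 (x axis) and KPNYN (y axis), with adrenergic and mesenchymal factors, neuronal structure and YAP/TAZ targets in colour; fitted values of genes without a count in one group depend on the prior count. The adrenergic core transcription factors had a median of -0.51 in SKNBE2 and -3.74 in KPNYN, and the YAP/TAZ targets 3.86 and 5.21.

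The lines differed in how far the neuroblast genes fell. The difference in log2 fold change, KPNYN minus SKNBE2, was -6.97 ± 0.14 for PHOX2A, -5.31 ± 0.25 for MYCN and -4.45 ± 0.09 for HAND2, each with an adjusted p of 1.9e-13 or less. For MYCN it was -6.25 without KPNYN doxycycline replicate 1 and -4.69 without replicate 2. It was -2.57 ± 0.09 for GATA3 and -2.10 ± 0.11 for ISL1. PRRX1 itself rose by 3.16 ± 0.14 more in KPNYN, and VIM (1.20 ± 0.08), FN1 (0.88 ± 0.08), NOTCH2 (1.05 ± 0.10) and SNAI2 (1.04 ± 0.12) also rose further there. Among GD2 synthesis genes the difference was -1.64 ± 0.28 for ST8SIA1, 0.88 ± 0.13 for ST3GAL5, 0.61 ± 0.14 for UGCG, -0.50 ± 0.13 for B4GALNT1, 0.48 ± 0.22 (adjusted p = 0.068) for B4GALT6 and -0.24 ± 0.09 for B4GALT5. The UGCG difference had an adjusted p of 0.087 by library size alone (1.5e-04 to 1.0 over all alternatives), and that of B4GALT5 lost its call with DESeq2 (adjusted p = 0.086), with DESeq2 size factors (0.055) and without SKNBE2 vehicle replicate 2 (0.086), SKNBE2 doxycycline replicate 1 (0.072) or 2 (0.056) or KPNYN doxycycline replicate 2 (0.14), with 1.2e-05 to 1.0 over all alternatives. EZH2 differed by -0.38 ± 0.09.

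The response differed between lines in 8925 genes, with a higher log2 fold change in KPNYN in 4270 (47.8%) and a lower one in 4655; by library size alone 25.9% of 9456 were higher, after a shift of -0.33 in the median over all genes. Of the 6817 genes that moved the same way, 3863 differed in size, 3381 of them larger in KPNYN. Among the largest negative differences were those at CNGB1 (2.49 to 10.7 CPM in SKNBE2), the non-coding RNA FENDRR (at least 147-fold lower in KPNYN; 0.697 to 4.59 CPM in SKNBE2) and LINC01105 (5.33 to 18.1 CPM in SKNBE2). The largest positive ones were at the coactivator EYA2 (at least 102-fold higher in KPNYN; 0.255 to 0.0550 CPM in SKNBE2), the ephrin receptor EPHA4 (289.9-fold higher, 95% counting interval 51.7 to 11487 in KPNYN; -1.87 ± 0.41 in SKNBE2), the ciliary gene EVC2 (at least 81.5-fold higher in KPNYN; 1.12 ± 0.22 in SKNBE2) and the GABA receptor subunit GABRA5 (6.07 ± 0.28 in KPNYN; -1.55 ± 0.55 in SKNBE2).

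By list, the difference between lines was negative for adrenergic factors, of which 2 were higher and 18 lower (2 and 18 adjusted over the list alone). Their median was -2.57 (camera adjusted p = 2.3e-06, adjusted p = 0.085 with an estimated correlation). Of the catecholamine genes, 1 was higher and 11 lower (1 and 11 adjusted over the list alone). The median was -4.22 (camera adjusted p = 3.7e-05, adjusted p = 0.12 with an estimated correlation). Among neuronal structure genes, 1 was higher and 15 lower (1 and 15 adjusted over the list alone). Their median was -4.86 (camera adjusted p = 2.2e-07, adjusted p = 0.085 with an estimated correlation). Of the surface antigens, 2 were higher and 9 lower (2 and 9 adjusted over the list alone). The median was -2.64 (camera adjusted p = 0.0012, adjusted p = 0.26 with an estimated correlation). The difference was positive for mesenchymal factors, of which 17 were higher and 5 lower (17 and 5 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 0.031, adjusted p = 0.22 with an estimated correlation; median 0.32 by library size alone, 13 higher and 7 lower). Of the epithelial-mesenchymal transition genes, 14 were higher and 2 lower (16 and 2 adjusted over the list alone). The median was 1.19 (camera adjusted p = 3.7e-05, adjusted p = 0.22 with an estimated correlation). Among YAP/TAZ targets, 10 were higher and 0 lower (10 and 0 adjusted over the list alone). Their median was 1.10 (camera adjusted p = 5.8e-04, adjusted p = 0.20 with an estimated correlation). Of MHC class I genes, 8 were higher and 0 lower (8 and 0 adjusted over the list alone). The median was 1.46 (camera adjusted p = 0.026, adjusted p = 0.34 with an estimated correlation). Among p53 targets, 9 were higher and 1 lower (9 and 1 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 8.5e-04, adjusted p = 0.12 with an estimated correlation; median 0.32 by library size alone, 7 higher and 1 lower). The difference was negative again for mitochondrially encoded genes, of which 0 were higher and 11 lower (0 and 11 adjusted over the list alone). The median was -0.58 (camera adjusted p = 0.019, adjusted p = 0.56 with an estimated correlation; median -0.91 by library size alone, 0 higher and 13 lower). These 10 of 30 lists passed with the preset correlation. With an estimated one camera called 0, 6 had an unadjusted p below 0.05, and fry called 26. Interferon-stimulated genes did not pass, as 1 was higher and 11 lower (2 and 11 adjusted over the list alone). Their median was -1.34 (camera adjusted p = 0.065). GD2 synthesis did not pass either, as 2 were higher and 3 lower (3 and 3 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.82; median -0.21 by library size alone, 1 higher and 3 lower). Median, mean and test differed in sign for GD2 synthesis (mean -0.07), AP-1 genes (median -0.08, mean 0.28, test up; median -0.41 by library size alone, 5 higher and 5 lower; median -0.04 with DESeq2 size factors), Schwann markers (median -0.04, mean -0.72, test up; median -0.37 by library size alone, median 0.00140 with DESeq2 size factors) and epithelial markers (median -0.89, mean -0.38, test up).

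**Figure D3:**
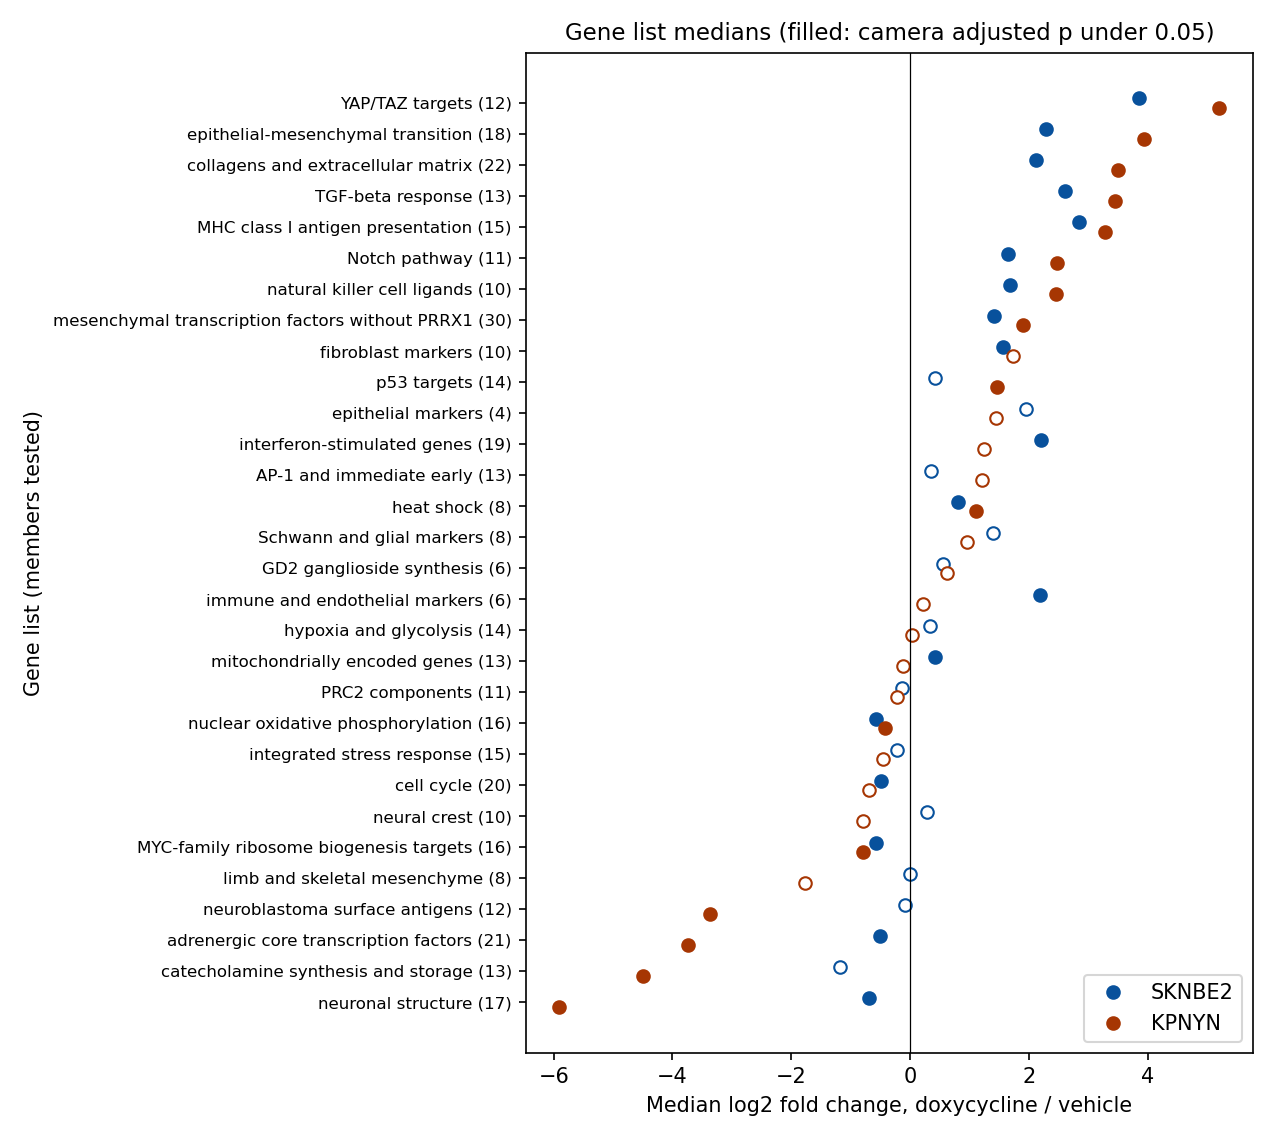
Median log2 fold change with doxycycline of each of the 30 fixed lists in SKNBE2 and KPNYN, with members without a count in one group set at their bound; filled points had a camera adjusted p below 0.05. Neuronal structure lay at -0.70 in SKNBE2 and -5.90 in KPNYN, and collagens and extracellular matrix at 2.12 and 3.49.

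With vehicle alone, the 2 lines differed from each other. FN1 was higher in KPNYN (944 ± 63.8 against 224 ± 0.500 CPM; log2 difference, KPNYN minus SKNBE2, 2.07 ± 0.06, adjusted p = 1.5e-16), and MYCN was lower (1071 ± 103 against 5381 ± 81.7 CPM; -2.33 ± 0.15, adjusted p = 4.3e-11). PRRX1 (-1.28 ± 0.13), HAND2 (-0.95 ± 0.06), PHOX2A (-0.28 ± 0.07) and VIM (-0.31 ± 0.06) were lower in KPNYN. ISL1 (0.65 ± 0.07), GATA3 (0.25 ± 0.06), SNAI2 (0.45 ± 0.09) and NOTCH2 (0.32 ± 0.08) were higher there, as were B4GALT6 (1.55 ± 0.16), ST8SIA1 (0.85 ± 0.15), B4GALNT1 (0.46 ± 0.09) and ST3GAL5 (0.35 ± 0.10) and EZH2 (0.21 ± 0.07), while B4GALT5 (-0.20 ± 0.06) was lower. The calls of B4GALT5, EZH2 and ST3GAL5 were lost without SKNBE2 vehicle replicate 1 (adjusted p = 0.064, 0.051 and 0.15; over all alternatives 0.0022 to 1.0, 0.0016 to 1.0 and 0.0013 to 1.0). With the replicate number as a block, the calls of PHOX2A, EZH2 and B4GALT5 were lost as well (adjusted p = 0.27, 0.055 and 0.054; PHOX2A over all alternatives 6.7e-06 to 1.0). The log2 difference was 0.22 ± 0.10 (adjusted p = 0.079) for UGCG. Of 16235 genes, 10232 differed, 5046 higher and 5186 lower in KPNYN.

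The largest differences were at genes that one line hardly expressed. SLFN11, a schlafen gene, averaged 102 CPM, the germline gene TDRD1 47.1 CPM, the keratin KRT17 20.9 CPM and the membrane protein gene ITM2A 17.1 CPM in vehicle-treated SKNBE2, and none had a count in either vehicle-treated KPNYN library. In KPNYN with vehicle the adaptor gene EFS averaged 54.7 CPM (0 in SKNBE2), the complement receptor C5AR1 15.6 CPM (0), the homeobox gene ALX1 15.4 CPM (0) and the matrix gene MXRA5 13.7 CPM (0). Adjusted p was 3.2e-12 or less for these genes.

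By list, TGF-beta response genes were higher in vehicle-treated KPNYN, as 11 were higher and 0 lower (11 and 0 adjusted over the list alone). Their median was 1.18 (camera adjusted p = 3.5e-04, adjusted p = 0.39 with an estimated correlation). Higher there as well were collagens and matrix, as 16 were higher and 4 lower (16 and 4 adjusted over the list alone). The median was 0.70 (camera adjusted p = 0.0036, adjusted p = 0.39 with an estimated correlation). Of the fibroblast markers, 7 were higher and 1 lower (7 and 1 adjusted over the list alone). Their median was 0.86 (camera adjusted p = 0.045, adjusted p = 0.39 with an estimated correlation). Among YAP/TAZ targets, 7 were higher and 2 lower (7 and 2 adjusted over the list alone). The median was 0.70 (camera adjusted p = 0.045, adjusted p = 0.39 with an estimated correlation). Of the p53 targets, 8 were higher and 2 lower (8 and 2 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 0.045, adjusted p = 0.39 with an estimated correlation). Of the mitochondrially encoded genes, 11 were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.91 (camera adjusted p = 5.1e-04, adjusted p = 0.39 with an estimated correlation). Cell cycle genes were lower, as 2 were higher and 14 lower (2 and 14 adjusted over the list alone). Their median was -0.38 (camera adjusted p = 0.0053, adjusted p = 0.39 with an estimated correlation). Of the MYC-family targets, 1 was higher and 11 lower (1 and 11 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.045, adjusted p = 0.39 with an estimated correlation). Heat shock genes were lower too, as 0 were higher and 6 lower (0 and 6 adjusted over the list alone). Their median was -0.32 (camera adjusted p = 0.045, adjusted p = 0.39 with an estimated correlation). Adrenergic factors did not pass, as 6 were higher and 12 lower (6 and 12 adjusted over the list alone). The median was -0.42 (camera adjusted p = 0.13). GD2 synthesis did not pass, as 4 were higher and 1 lower (4 and 1 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.18). Interferon-stimulated genes (median 0.03, mean -0.04, test up; median 0.09 by library size alone, 6 higher and 4 lower; median 0.02 with DESeq2 size factors) and surface antigens (median 0.24, mean -0.26, test up) differed in sign between median and mean. Of 30 lists, 9 passed with the preset correlation. With an estimated one camera called 0, 1 had an unadjusted p below 0.05, and fry called 23. The number passing was 4 by library size alone, 4 without SKNBE2 doxycycline replicate 1 or 2, and 5 without SKNBE2 vehicle replicate 1, KPNYN vehicle replicate 1, or KPNYN doxycycline replicate 1 or 2.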

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

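The tests of library scaling, of the PRRX1 level and of unconverted cells were chosen only after the result was seen, and the test of one uniform share also after the spread it builds on was known; for cells of another line the share of variance was chosen before and the SD in log2 units after. Each result here stood out because the response to doxycycline differed between the 2 lines in a test of the difference itself (edgeR's interaction contrast for genes, camera on that contrast for lists). The difference, KPNYN minus SKNBE2 on the log2 scale (± SE), was 3.16 ± 0.14 for PRRX1, 1.20 ± 0.08 for VIM, 1.05 ± 0.10 for NOTCH2, 1.04 ± 0.12 for SNAI2, 0.88 ± 0.08 for FN1, 0.88 ± 0.13 for ST3GAL5 and 0.61 ± 0.14 for UGCG. It was negative for the sympathetic neuroblast regulators and MYCN, with -6.97 ± 0.14 for PHOX2A, -5.31 ± 0.25 for MYCN, -4.45 ± 0.09 for HAND2, -2.57 ± 0.09 for GATA3 and -2.10 ± 0.11 for ISL1; MYCN had -6.25 without KPNYN doxycycline replicate 1 and -4.69 without replicate 2. Smaller negative differences were -1.64 ± 0.28 for ST8SIA1, -0.50 ± 0.13 for B4GALNT1, -0.38 ± 0.09 for EZH2 and -0.24 ± 0.09 for B4GALT5.

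Genes near 0 counts in one group differed as well, and for these the adjusted p is given because their fitted differences depend on the prior count. The response was lower in KPNYN for CNGB1 (adjusted p = 4.7e-14), FENDRR (adjusted p = 2.6e-12) and LINC01105 (adjusted p = 2.2e-14), and higher there for EYA2 (adjusted p = 6.4e-07), EPHA4 (adjusted p = 1.7e-09), EVC2 (adjusted p = 3.8e-08) and GABRA5 (adjusted p = 5.0e-09). Among lists, the median difference was -4.86 for neuronal structure, -4.22 for catecholamine genes, -2.64 for surface antigens, -2.57 for adrenergic factors and -0.58 for mitochondrially encoded genes. It was 1.46 for MHC class I genes, 1.19 for epithelial-mesenchymal transition, 1.10 for YAP/TAZ targets, and 0.65 and 0.65 for mesenchymal factors and p53 targets. By library size alone the last 2 were 0.32 and 0.32, and that of mitochondrially encoded genes -0.91. These lists had an adjusted p = 0.085 to 0.56 with an estimated correlation. The response differed in 8925 genes in all.

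The first pattern was the near loss of adrenergic and neuronal genes in KPNYN with doxycycline, where the median log2 fold change over 38 members of both lists was -4.31. Cells of another line in these cultures could give such a loss, and they would bring copy-number differences, which move neighbouring genes together. Log2 fold changes were ranked and turned into normal scores, and the share of the variance of these scores between windows was estimated. Over 56 windows of 200 neighbouring genes, that share was 1.85% for the KPNYN response (95% bootstrap interval 0.661% to 3.37%). It was 15.8% (8.42% to 22.8%) between the vehicle-treated lines. The ratio of these shares, 0.117 (0.0403 to 0.267), lay under the bound of 0.5 set for excluding the explanation. The bound was set on the wrong quantity, because a share falls as the rest of the response grows. Before ranking, log2 fold changes had a variance of 4.33 in KPNYN against 1.04 between the lines. In log2 units the SD between windows was 0.172 in KPNYN and 0.304 between the lines, a ratio of 0.566 (0.247 to 0.951). For the SKNBE2 response that ratio was 0.449 (0.257 to 0.700). SDs of window medians were 0.188, 0.301 and 0.128 in KPNYN, between the lines and in SKNBE2. These values therefore cannot tell cells of another line from a KPNYN response. Library scaling moves all genes alike. The median was -4.31 with DESeq2 size factors and -4.63 by library size alone, against -0.05 and -0.38 over all genes. This argued against scaling as the whole cause. PRRX1 with doxycycline was 3.68 times as high in KPNYN as in SKNBE2. With 2 lines, a fall that grows with the PRRX1 level cannot be told from their other differences.

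The second pattern was the smaller fall of the same kind of genes in SKNBE2. Over 498 genes with at least 5 CPM in vehicle-treated SKNBE2 that fell over 16-fold in KPNYN, the median log2 fold change in SKNBE2 was -0.71, equal to 61.2% of the vehicle level, with 52 that rose, 359 that fell and 87 that did not pass. If converted cells lost these genes as far as KPNYN did, one uniform share of unconverted cells as the whole cause would leave these genes at one residual level, yet 70.1% of them (349, against 22.7 by chance) lay over 2 SE from the median, which argued against that form of it. A share of unconverted cells as part of the cause remained open: the interquartile range was 0.985, just short of the 1 set as the bound for excluding it, and it cannot be told apart from a partial response of every cell with RNA pooled over cells. A weaker response of this line at its lower PRRX1 level is an untested biological alternative.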

How the results depend on the processing

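No alternative was added after the results were seen. No single gene named by the fixed rule changed sign under any alternative tried, and the correlation between lines stayed positive. The balance of calls, near 50% upward in each comparison, turned under some. In SKNBE2 52.4% were upward, but 48.6% with DESeq2 size factors and 49.4% with DESeq2. For genes whose doxycycline response differs between lines, 47.8% became 50.9% with DESeq2 size factors and 51.6% with the DESeq2 Wald test. Between vehicle-treated lines 49.3% became 53.7% by library size alone, 50.0% with at least 5 CPM in 2 libraries and 55.0% against a log2 fold change of 1, where KPNYN went from 48.9% to 52.7%; the cause was not tested. Some reported list and family medians near 0 changed sign with the scaling. By library size alone the median difference between lines went from 0.12 to -0.21 for GD2 synthesis and from 0.10 to -0.22 for cytosolic ribosomal proteins; for Schwann markers it went from -0.04 to 0.00140 with DESeq2 size factors. The hypoxia median in KPNYN went from 0.03 to -0.29 by library size alone (5 rose and 6 fell), and that of synaptotagmins in SKNBE2 from 0.000397 to -0.04 with DESeq2 size factors. Single-gene results kept their side of the threshold 1933 times over all alternatives, lost a call 50 times (33 of them against a log2 fold change of 1, 10 without 1 library, 2 with DESeq2) and gained one 11 times. Counts of called genes stayed within 1.5 times of those reported under every alternative except the test against a log2 fold change of 1, a stricter question by construction. It called 2135 genes in SKNBE2 (85.7% upward), 5146 in KPNYN (52.7%), 2808 for the difference between lines (31.9%), 1987 between vehicle-treated lines (55.0%) and 1520 for the overlap of called genes between lines, counted in the same direction. With 1 library left out, the remaining library of that group is assumed to vary like the other groups; the counts then ran from 8314 to 10186 in SKNBE2, 11230 to 12173 in KPNYN, 8066 to 8952 for the difference, 8952 to 10170 between vehicle-treated lines and 6028 to 6916 for the overlap. DESeq2 size factors kept 9349 of the SKNBE2 calls and 12095 of those in KPNYN. Library size alone kept 10658 of the KPNYN calls, 41 of them with the opposite sign, and 7101 of those for the difference.

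The number of lists called was 0 in SKNBE2, 0 in KPNYN, 0 for the difference and 0 between vehicle-treated lines with a correlation estimated by camera, where 12, 10, 6 and 1 had an unadjusted p below 0.05; fry, which compares a list with no other genes, called 29, 28, 26 and 23. Leaving out 1 library gave 16 to 20 lists in SKNBE2, 15 to 17 in KPNYN and 10 to 13 for the difference. Between vehicle-treated lines the 9 called lists became 4 by library size alone and 4 to 10 with 1 library left out. The cause was not tested. The correlation of fold changes between lines (0.543 in the report) was 0.436 with DESeq2, 0.406 without the low-count filter, 0.590 with at least 5 CPM in 2 libraries, 0.591 with each line fitted alone and 0.495 to 0.536 with 1 library left out; the cause was not tested. The PRRX1 log2 fold change ran from 5.96 to 6.17 in SKNBE2 and 9.09 to 9.41 in KPNYN with 1 library left out.

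Replicate numbers in the labels are shared by the groups, but nothing says that a number marks a shared culture or day, and the deviations of same-numbered samples correlated at 0.0241 in SKNBE2 and -0.0618 in KPNYN across genes. With the number as a replicate block, 9438 genes were called in SKNBE2, 11970 in KPNYN, 8757 for the difference and 8892 between vehicle-treated lines. Lists called between vehicle-treated lines became 5. B4GALNT1 in KPNYN had an adjusted p of 0.045 with the block (4.1e-05 to 1.0 over all alternatives). Apart from PHOX2A, EZH2 and B4GALT5 between vehicle-treated lines, the block changed no other call of a gene named by the fixed rule.

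The lactosylceramide synthase B4GALT6 passed for the difference between lines with DESeq2 size factors (adjusted p = 0.046) and without SKNBE2 vehicle replicate 1 (0.029; 0.029 to 1.0 over all alternatives), and UGCG passed between vehicle-treated lines by library size alone (0.030) and with at least 5 CPM in 2 libraries (0.046; 0.030 to 1.0). Depth limited genes near the floor of 3 counts, whose folds are bounds or carry wide counting intervals.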

Other observations

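The gene families here, set by gene symbol, and the tests of library scaling and of MYCN were chosen only after the data were seen, the bound for scaling being extended to every scaling after its first value; the transcript length test was chosen before its result. Of 21 families defined, those named are described, and p-values are adjusted over the families. Of 25 genes with integrin symbols, 18 rose and 4 fell (median 2.08, camera adjusted p = 3.0e-05, adjusted p = 0.15 with an estimated correlation) in SKNBE2 and 19 rose and 6 fell (median 2.66, camera adjusted p = 0.0013, adjusted p = 0.21 with an estimated correlation) in KPNYN; 4 of them (ITGB3BP, ITGB1BP1, ITGB1BP2 and ITGBL1) are not integrin subunits. The laminin receptor subunit ITGA3 had log2 fold changes of 4.26 ± 0.08 and 5.76 ± 0.09 in SKNBE2 and KPNYN. Of 11 annexins, which bind membrane phospholipids, 10 rose and 0 fell (median 1.80, camera adjusted p = 1.9e-04, adjusted p = 0.15 with an estimated correlation) in SKNBE2 and 9 rose and 0 fell (median 3.36, camera adjusted p = 7.1e-04, adjusted p = 0.21 with an estimated correlation) in KPNYN, as did ANXA5 (1.91 ± 0.06 and 3.36 ± 0.07). Of 10 calcium-binding S100 genes, 8 rose and 0 fell (median 1.88, camera adjusted p = 0.0017, adjusted p = 0.15 with an estimated correlation) in SKNBE2 and 9 rose and 1 fell (median 4.60, camera adjusted p = 0.0024, adjusted p = 0.21 with an estimated correlation) in KPNYN, such as S100A6 (2.50 ± 0.09 and 4.59 ± 0.12) and the annexin partner S100A10 (1.76 ± 0.10 and 7.76 ± 0.16). Of 5 chemokines, 4 rose and 0 fell (median 3.78, camera adjusted p = 0.012, adjusted p = 0.17 with an estimated correlation) in SKNBE2 and 4 rose and 0 fell (median 4.84, camera adjusted p = 0.048, adjusted p = 0.21 with an estimated correlation) in KPNYN, with the monocyte attractant CCL2 (5.52 ± 0.15 and 5.58 ± 0.24) and the neutrophil attractant CXCL8 (6.55 ± 0.19 and 8.77 ± 0.22). Of 16 genes with interleukin symbols, 4 of them receptors (IL4R, IL6R, IL7R and IL21R), 11 rose and 2 fell (median 2.19, camera adjusted p = 0.0056, adjusted p = 0.15 with an estimated correlation) in SKNBE2 and 10 rose and 4 fell (median 2.42, camera adjusted p = 0.039, adjusted p = 0.21 with an estimated correlation) in KPNYN, including the cytokine IL1B (4.45 ± 0.15 and 7.78 ± 0.12). Of 14 matrix metalloproteinases, 9 rose and 1 fell (median 1.39, camera adjusted p = 0.0056, adjusted p = 0.26 with an estimated correlation) in SKNBE2 and 8 rose and 2 fell (median 1.04, camera adjusted p = 0.026, adjusted p = 0.44 with an estimated correlation) in KPNYN, including the collagenase MMP1 (5.11 ± 0.08 and 8.51 ± 0.10).

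Of 28 voltage-gated potassium channel genes, 7 rose and 14 fell (median -0.61, camera adjusted p = 0.056) in SKNBE2 and 4 rose and 20 fell (median -3.46, or -3.23 with members at 0 set to their bound, camera adjusted p = 0.0013, adjusted p = 0.21 with an estimated correlation) in KPNYN, and the difference between lines passed, as 3 were higher and 19 lower (median -3.69, camera adjusted p = 0.0059, adjusted p = 0.38 with an estimated correlation). Of 18 voltage-gated calcium channel subunit genes, 8 rose and 6 fell (median 0.15, camera adjusted p = 0.99) in SKNBE2 and 7 rose and 11 fell (median -1.27, camera adjusted p = 0.32) in KPNYN. Of 15 synaptotagmins, calcium sensors of vesicle release, 6 rose and 3 fell (median 0.00, camera adjusted p = 0.64) in SKNBE2 and 1 rose and 10 fell (median -2.53, camera adjusted p = 0.013, adjusted p = 0.21 with an estimated correlation) in KPNYN, and for the difference 1 was higher and 11 lower (median -2.86, camera adjusted p = 0.0059, adjusted p = 0.38 with an estimated correlation); SYT7 rose in SKNBE2 and fell in KPNYN (1.42 ± 0.10 and -7.13 ± 0.16). With vehicle alone HOX genes were lower in KPNYN than in SKNBE2, as of 16 genes 1 was higher and 14 lower (median -1.43, camera adjusted p = 4.9e-04, adjusted p = 0.13 with an estimated correlation), and clustered protocadherins, adhesion molecules of neurons, were higher, as of 53 genes 27 were higher and 8 lower (median 0.80, camera adjusted p = 0.016, adjusted p = 0.39 with an estimated correlation); copies within that cluster are similar enough to share reads.

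Cytosolic ribosomal protein genes were lower with doxycycline in both lines: of 82, 2 rose and 76 fell (median -0.64, camera adjusted p = 6.6e-16, adjusted p = 0.26 with an estimated correlation) in SKNBE2 and 5 rose and 72 fell (median -0.55, camera adjusted p = 5.1e-07, adjusted p = 0.47 with an estimated correlation) in KPNYN, for example RPS3 (-0.97 ± 0.06 and -0.71 ± 0.06) and RPL23A (-0.77 ± 0.06 and -1.58 ± 0.06), with the reservation that their many pseudogenes can take reads. Short transcripts could respond to RNA quality. Against 20 genes each, matched on transcript length and expression, the ribosomal protein genes lay at -0.39 in SKNBE2 and -0.43 in KPNYN. The 95% bootstrap intervals were -0.49 to -0.34 and -0.54 to -0.29. Intervals in this paragraph resample genes, which moved together (estimated correlation 0.485), and leave out the spread between libraries. In these libraries the values argued against length as the whole cause. Library scaling was left open by its test: the distance below the median of all genes was -0.499 or lower in both lines, but scaling moves all genes alike and leaves such a distance as it is. With TMM, DESeq2 size factors and library size alone the median itself was -0.64, -0.68 and -0.64 in SKNBE2 and -0.55, -0.55 and -0.88 in KPNYN. MYCN, which drives ribosome biogenesis, fell further in KPNYN. A ribosomal fall in proportion to that of MYCN on the log2 scale would have needed a median difference, KPNYN minus SKNBE2, of -1.91 with TMM, -1.97 with DESeq2 size factors and -2.02 by library size alone. With 95% bootstrap intervals over genes, it was 0.10 (0.01 to 0.17), 0.15 (0.06 to 0.21) and -0.22 (-0.31 to -0.16), which argued against proportion in these libraries. A link to MYCN of another form and other consequences of PRRX1 were not tested.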
